A study of Mus musculus with 12 samples.

How the data were processed

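Lung RNA of OVA-treated mice and of a placebo pool was measured on 12 2-colour oligonucleotide arrays with 45018 features each, 4 arrays in each of 3 groups. According to the study's design text, 1000 ng of total RNA per OVA-treated sample was labelled with Cy5 and the pooled RNA of the placebo group with Cy3. The sample labels differ from it: they give total RNA for the Cy3 channel but polyA RNA for the Cy5 channel, or nothing for the Cy5 channel of ova1_4h replicate 1. The design text was followed. The 4 arrays of a group are called biological replicates in the labels and come from groups of 6 mice, and that each array holds 1 mouse is inferred from those words only. Replicate numbers are those of the sample titles, while the description of ova1_4h replicate 4 calls it the third sample. The deposited values are log10 ratios of the 2 channels, normalised per the labels with Agilent Feature Extraction 7.5 under the dual color microarray protocol 5.5. The background correction, the filters and any centring are not given in the sources used here. The log10 scale was inferred from the values: features without a listed gene formed tight clusters on all arrays, among them 32 at a mean of -0.809 and 42 at 0.968, as spike-in transcripts at fixed ratios give on a log10 scale. The direction, OVA-treated lung over placebo pool, follows from the dyes in the labels and the convention of that software and is not written with the values.

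No value was missing, and the median of each array was 0. Between 15% and 23.2% of the features of an array were at exactly 0, and 3866 features were at 0 on all arrays, which brings the affected genes closer to 0 and narrows their spread. Signal intensities were not analysed here, so signal over background is unknown and dim features could not be removed by it. Values were multiplied by 3.3219 to give log2 ratios. Features with exactly 1 gene symbol (33653) were averaged per gene, which gave 19087 genes, 10744 from 1 feature and 8343 from several; 56 features with several symbols and 11309 without a listed gene were left out of the gene tests. Gene symbols were checked against an annotation table through Entrez numbers, found for 33517 features (99.6%), and 0 symbols changed. No genome came with the series, so positions are not given. Of the genes tested, 720 were at exactly 0 on all arrays.

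Each group was compared with the placebo pool by testing its mean log2 ratio against 0, and the groups were compared with each other, in 1 linear model over all 12 arrays with a mean per group (limma 3.58.1 in R 4.3.3, empirical Bayes moderation, 9.88 total degrees of freedom). P-values were adjusted by the method of Benjamini and Hochberg over the 19087 genes of each of the 6 comparisons, all tests were two-sided, and a gene was called at an adjusted p under 0.05. The SE is the moderated standard error of the fit. The pool is a single sample, so tests against it leave out the spread between placebo mice, and no dyes were swapped, so a gene-specific dye bias or a peculiarity of the pool adds to every change against the pool. Both cancel between OVA groups. All 3 comparisons with the pool share that control and are not independent of each other.

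A set of 42 gene lists, for pathways of allergic inflammation, cell types of the lung and tissues that can be carried along with it, was written before the data were examined, as were the groups, the tests, the rule for named genes and most of the other settings tried. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over 252 tests of 42 lists in 6 comparisons, which called 125. With a correlation estimated for each list instead, camera called 0, with 26 at an unadjusted p under 0.05 and 0.448 as the smallest adjusted p. Counts of called list members use the adjustment over all genes, and those adjusted over the list alone use an adjustment within the list. Members without a measured feature were not analysed here, and 19 genes stand in more than 1 list.

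Named genes were taken by a rule: Pon1; the 10 called genes with the largest rise and the 10 with the largest fall per comparison that had the same sign on all 4 arrays, or no overlap of the arrays between groups, leaving out clone names; and up to 4 called genes per list, or 2 as values where none was called. The text uses a part of these. Pon3 and the Pon1 features were named because the title asks about paraoxonase-1. The named genes called between OVA groups showed no overlap between the arrays except for 4 genes in ova3_24h against ova1_4h that are not named there. The rule required this of the genes with the largest changes, and a call on the same arrays favours it for the list genes. It is therefore no separate support for them.

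The model was tested on simulated data of the same size. For ova3_24h against control it recovered 80.6%, 95.5% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale with 9 false calls among 19087 genes, and for ova3_4h against ova1_4h 52.2%, 79.1% and 98.5% with 8 false calls. Camera called the 1 shifted list and 0 of 20 random lists. The simulated noise was normal and independent between genes, without a shared pool error or dye bias. These rates therefore need not hold for the data, least of all against the pool.

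The alternatives chosen then were centring each array on its median, quantile normalization between arrays, testing each feature on its own, leaving out genes at 0 on 6 or more arrays, keeping only genes with all values, leaving out the genes in the lowest quartile of spread, robust moderation, array weights, fitting only the groups compared, the replicate number as a block, leaving out each array in turn, an estimated correlation for the lists and a 2-fold minimum for shared calls. Added after the data were seen were leaving out features at 0 on 6 or more arrays before averaging and leaving out the 2 arrays with a response slope under 0.7. The response slope of an array is the regression of its log2 values on the mean of the other 3 arrays of its group, over genes with a mean beyond 1 in either direction. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.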

Results

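Lung RNA of mice with an allergic airway response was compared with that of placebo-treated mice on 12 2-colour oligonucleotide arrays. The allergen was ovalbumin (OVA), the egg white protein to which the mice were sensitised before repeated challenge, and control mice received phosphate-buffered saline instead. Each array carried Cy5-labelled RNA of OVA-treated lung against Cy3-labelled RNA of a common pool of placebo lungs. There were 3 groups of 4 arrays. Group ova1_4h was taken 4 h after challenge 1, on day 28 (replicates 1, 2, 4 and 5), group ova3_4h 4 h after challenge 3, on day 30 (replicates 1 to 4), and group ova3_24h 24 h after challenge 3, on day 31 (replicates 2 to 5). The study's title asks about a role of paraoxonase-1, the product of Pon1, in asthma. All changes below are log2 changes ± SE with n = 4 arrays per group, and a gene was called at an adjusted p under 0.05 by limma. The SE uses a spread shared over all 12 arrays, so it does not show how the spread differs between groups. In ova1_4h, for example, Mt2 had an SD of 1.59 over its arrays and an SE of 0.49. Arg1 in ova3_4h had an SD of 0.172 and an SE of 0.41. The called genes taken by the rule for named genes moved in the stated direction on all 4 arrays of their group, which the rule itself required of those with the largest changes.

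Between 6745 and 10450 of the 45018 features per array were listed at exactly 0, and the number of arrays limits the precision. The arrays differed in the strength of their response. The slope of an array's gene changes on the mean of the other 3 arrays of its group was 0.565 on ova1_4h replicate 2 and 0.62 on ova3_24h replicate 5, against 0.873 to 1.18 on the other 10 arrays. Both stayed in their groups, and each total of called genes below is also given without them, a choice made after the data were seen. An array outside the groups compared acts on a total only through the spread that the fit shares over all arrays.

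Pon1, which encodes a serum esterase and lactonase carried on high-density lipoprotein, fell by 1.20 ± 0.24 in ova3_4h (2.30-fold lower than the placebo pool, adjusted p = 0.0018) and by 1.68 ± 0.24 in ova3_24h (3.21-fold lower, adjusted p = 0.000295). After challenge 1 its change was -0.34 ± 0.24 (adjusted p = 0.305). The gene value is a mean over 2 features that behaved differently. Feature 26139 fell by 3.11 ± 0.31 in ova3_4h and by 3.10 ± 0.31 in ova3_24h, 8.63-fold and 8.59-fold lower (adjusted p = 2.77e-05 and 3.85e-05), and its change in ova1_4h was -0.71 ± 0.31 (adjusted p = 0.0995). Feature 30576 was at exactly 0 on 5 arrays and not called in any group, with means of 0.03, 0.71 and -0.26; ova3_4h replicate 1 alone was at 2.50. Pon2, an intracellular member of the family, fell by 0.29 ± 0.03, 0.39 ± 0.03 and 0.25 ± 0.03 in ova1_4h, ova3_4h and ova3_24h (adjusted p = 0.000136, 1.1e-05 and 0.000193), although 1 of its 4 features was not called. Pon3 fell by 0.14 ± 0.05 in ova1_4h (adjusted p = 0.0334), and its changes of 0.02 ± 0.05 and 0.05 ± 0.05 in ova3_4h and ova3_24h were not called (adjusted p = 0.813 and 0.385).

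Between the OVA groups, Pon1 fell by 1.34 ± 0.34 from ova1_4h to ova3_24h (adjusted p = 0.019). That call was lost without ova1_4h replicate 1 (adjusted p = 0.0501), ova3_24h replicate 2 (0.0551) or ova3_24h replicate 4 (0.0561). It was also lost with the replicate number as a block (-1.19, adjusted p = 0.0568). The change of -0.86 ± 0.34 from ova1_4h to ova3_4h was not called (adjusted p = 0.112), but it was without ova3_4h replicate 1 (-1.19, adjusted p = 0.0223). Feature 26139 alone fell by 2.40 ± 0.44 from ova1_4h to either later group (adjusted p = 0.00766 for ova3_4h and 0.00476 for ova3_24h). From ova3_4h to ova3_24h the change in Pon1 was -0.48 ± 0.34 (adjusted p = 0.492).

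**Figure D1:**
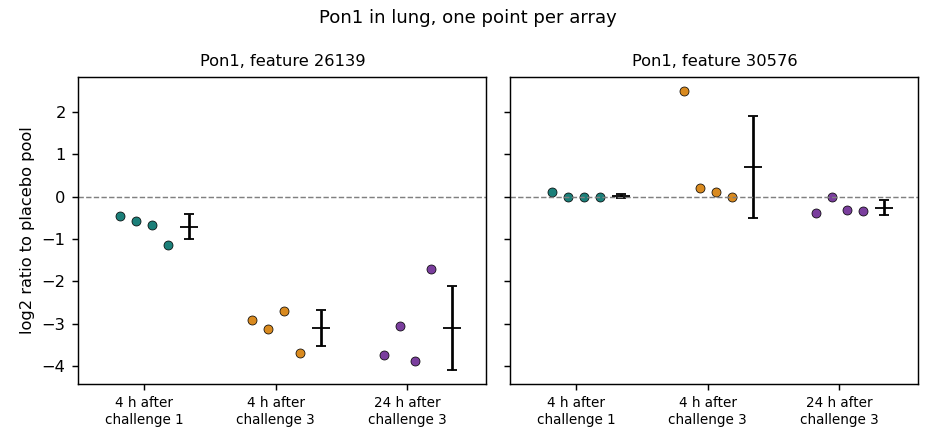
Log2 ratio of OVA-treated lung over the placebo pool for the 2 features of Pon1, with a point per array and the mean ± SD of each group of 4 arrays. Feature 26139 lay between -3.89 and -1.72 on the 8 arrays taken after challenge 3, and feature 30576 was at exactly 0 on 5 of the 12 arrays.

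The comparison of ova1_4h with the placebo pool asks what sensitisation and 1 challenge had changed after 4 h. Chemokines led the response. Cxcl3, a neutrophil attractant, rose by 6.29 ± 0.28 (78.5-fold, adjusted p = 1.3e-06), the monocyte attractants Ccl7 and Ccl2 by 4.97 ± 0.18 and 4.06 ± 0.14, and the interferon-induced Cxcl10 and Cxcl11 by 4.84 ± 0.16 and 4.27 ± 0.24. Cxcl1 rose by 4.33 ± 0.34, Cxcl5 by 4.30 ± 0.54, and Ccl11, which encodes the eosinophil attractant eotaxin, by 3.32 ± 0.37. Of 17 CC chemokines measured 14 rose and 2 fell, and of 14 CXC chemokines 12 rose and 1 fell, with the same counts adjusted over the list alone. These lists had adjusted p = 7.26e-09 and 1.14e-07 by camera, and each had adjusted p = 0.448 with an estimated correlation.

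Acute phase genes rose with them. Saa3 and Saa1, which encode serum amyloid A proteins, rose by 4.97 ± 0.21 (31.3-fold) and 4.48 ± 0.16 (22.3-fold), and the metallothionein Mt2 by 4.43 ± 0.49. Of 25 acute phase and NF-kB response genes 24 rose, also when adjusted over the list alone (adjusted p = 3.83e-15; adjusted p = 0.448 with an estimated correlation). Neutrophil markers rose in 14 of 16 cases, again in 14 adjusted over the list alone, with the granule genes Camp and Ngp up by 2.26 ± 0.25 and 1.68 ± 0.17 (adjusted p = 2.05e-09; adjusted p = 0.448 with an estimated correlation). Interferon response genes were higher in 19 of 23 cases, and in 20 adjusted over the list alone, among them Rsad2 (1.32 ± 0.18) and Gbp2 (1.24 ± 0.09); their adjusted p = 2.31e-09 became adjusted p = 0.448 with an estimated correlation. Among 14 macrophage and monocyte markers 10 rose and 1 fell, the same as adjusted over the list alone, with the endotoxin co-receptor Cd14 up by 2.39 ± 0.15 (adjusted p = 0.00147; adjusted p = 0.448 with an estimated correlation).

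The type 2 programme was already present at this time. Il5, the eosinophil growth factor, rose by 3.06 ± 0.40, Il4 by 2.33 ± 0.35 and the epithelial alarmin Il33 by 1.87 ± 0.27. In the list of Th2 cytokines and receptors 8 of 18 members rose and 1 fell, and the counts were the same adjusted over the list alone (adjusted p = 0.0247; adjusted p = 0.531 with an estimated correlation). Slc26a4, which encodes the anion exchanger pendrin, rose by 5.21 ± 0.21 (36.9-fold) and the goblet cell gene Clca1 by 3.52 ± 0.24 (11.5-fold). Of 14 goblet cell and mucus genes 10 rose, and adjusted over the list alone 10 rose and 1 fell (adjusted p = 4.94e-05; adjusted p = 0.455 with an estimated correlation). Retnla and Arg1, markers of alternatively activated macrophages, rose by 4.24 ± 0.25 and 2.51 ± 0.41; 9 of the 17 genes of that list rose, and 10 adjusted over the list alone (adjusted p = 0.000215; adjusted p = 0.551 with an estimated correlation). On ova1_4h replicate 2 the means of the Th2 and alternatively activated macrophage lists were 0.276 and 0.391, against 0.783 and 1.19 on the other 3 arrays. The basophil protease Mcpt8 rose by 2.96 ± 0.19, while 4 of the 12 mast cell and basophil markers rose and 1 fell, also adjusted over the list alone, and the list was not called (adjusted p = 0.152).

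Natural killer (NK) cell genes fell, as did a few genes of the eosinophil list, which in whole-lung RNA need not come from eosinophils. Siglecf fell by 1.25 ± 0.16 and Rnase2a, a member of a family of near-identical eosinophil ribonucleases that a single feature need not separate, fell by 1.37 ± 0.22. Of 10 eosinophil markers 1 rose and 3 fell, also adjusted over the list alone, and the list was not called (adjusted p = 0.281). The NK receptor genes Klra8 and Klrd1 fell by 0.91 ± 0.09 and 0.78 ± 0.06; 11 of the 14 NK cell and cytotoxic markers fell and 1 rose, with equal counts adjusted over the list alone (adjusted p = 0.00284; adjusted p = 0.531 with an estimated correlation). Xenobiotic metabolism genes fell in 11 of 22 cases and 1 rose, or 15 and 1 adjusted over the list alone, with the carboxylesterase gene Ces1f at -1.51 ± 0.15 (adjusted p = 0.00181; adjusted p = 0.574 with an estimated correlation). Among the largest decreases were those in Bex2 (-2.63 ± 0.27), Xlr3c (-2.43 ± 0.35), the potassium channel gene Kcna5 (-2.22 ± 0.48), Glycam1 (-2.18 ± 0.26), Krtap17-1 (-2.10 ± 0.30) and the glycogen synthase gene Gys2 (-1.93 ± 0.38).

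In total, 7734 of 19087 genes were called in ova1_4h against the placebo pool, 3520 higher and 4214 lower. Of these, 303 were higher and 116 lower by at least 2-fold. Without the 2 arrays of weaker response the total was 8238, and in a fit of this group's 4 arrays alone it was 4720. Dye and pool differences cannot be separated from treatment in any comparison with the placebo pool. Control mice were sampled on day 31, not on day 28, and had an airway measurement that ova1_4h did not share.

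The comparison of ova3_4h with the placebo pool asks what the lung expressed 4 h after repeated challenge. The largest rises among the named genes were in Clca1 and Slc26a4, both of the goblet cell and mucus list. Clca1 rose by 8.89 ± 0.24 (473-fold, adjusted p = 6.95e-08), Slc26a4 by 6.31 ± 0.21 (79.4-fold) and Agr2, a secretory-pathway disulfide isomerase of mucous cells, by 4.84 ± 0.21. All 14 goblet cell and mucus genes rose, also when adjusted over the list alone (adjusted p = 2.93e-11; adjusted p = 0.448 with an estimated correlation). The chitinase-like genes Chil3 and Chil4 rose by 5.54 ± 0.27 and 5.12 ± 0.30, Arg1 by 5.38 ± 0.41 and Retnla by 5.12 ± 0.25. All 17 alternatively activated macrophage genes rose, by either adjustment including that adjusted over the list alone (adjusted p = 2.93e-11; adjusted p = 0.448 with an estimated correlation). Fxyd4, an ion transport regulator, rose by 5.25 ± 0.24.

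Proliferation genes rose as a whole list. Birc5 rose by 3.25 ± 0.18 (9.49-fold), Aurkb by 3.21 ± 0.23 and Mki67, the gene of the Ki-67 proliferation antigen, by 2.99 ± 0.17. All 29 cell cycle genes rose, also adjusted over the list alone (adjusted p = 5.62e-16; adjusted p = 0.448 with an estimated correlation). Chemokines stayed high, with Ccl8 up by 5.80 ± 0.24 (55.6-fold), Cxcl11 by 5.16 ± 0.24, Cxcl10 by 5.12 ± 0.16 and Ccl11 by 4.79 ± 0.37. Of 17 CC chemokines 15 rose and 1 fell, with the same counts adjusted over the list alone, and of 14 CXC chemokines 11 rose, or 12 adjusted over the list alone (adjusted p = 9.37e-08 and 1.13e-05; each adjusted p = 0.448 with an estimated correlation). Th2 cytokines and receptors rose in 12 of 18 cases and 1 fell, as they did adjusted over the list alone, with Il5 up by 3.83 ± 0.40 and Il4 by 3.18 ± 0.35 (adjusted p = 0.00488; adjusted p = 0.513 with an estimated correlation).

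Several leukocyte and complement lists were higher. Rnase2a rose by 3.06 ± 0.22, Prg2, which encodes eosinophil major basic protein, by 2.24 ± 0.28, and the lipoxygenase gene Alox15 by 2.90 ± 0.20. Of 10 eosinophil markers 6 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.0231; adjusted p = 0.531 with an estimated correlation), and of 21 eicosanoid metabolism genes 11 rose and 2 fell, again the same adjusted over the list alone (adjusted p = 0.00477; adjusted p = 0.448 with an estimated correlation). The complement genes Cfp (properdin) and C1qb rose by 2.39 ± 0.11 and 2.02 ± 0.14; 10 of the 13 genes of that list rose, also adjusted over the list alone (adjusted p = 5.42e-06; adjusted p = 0.448 with an estimated correlation). Batf3, a transcription factor of cross-presenting dendritic cells, rose by 2.57 ± 0.12, and 10 of 14 dendritic cell markers rose and 2 fell, unchanged when adjusted over the list alone (adjusted p = 0.00131; adjusted p = 0.531 with an estimated correlation). The invariant-chain protease Ctss rose by 2.00 ± 0.14; 8 of 11 genes of MHC class II presentation rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.0036; adjusted p = 0.558 with an estimated correlation).

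Xenobiotic metabolism, alveolar type I, endothelial and cardiac muscle genes fell. Cyp2a5 and Cyp2f2, cytochrome P450 genes of the airway epithelium, fell by 2.40 ± 0.17 and 2.24 ± 0.23 and the glutathione transferase Gstm1 by 1.24 ± 0.14. Of 22 xenobiotic metabolism genes 18 fell and 2 rose, or 19 and 2 adjusted over the list alone (adjusted p = 0.00031; adjusted p = 0.531 with an estimated correlation). The alveolar type I genes Akap5 and Hopx fell by 1.04 ± 0.18 and 0.96 ± 0.10, and 9 of 10 markers of that cell type fell, also adjusted over the list alone (adjusted p = 0.00492; adjusted p = 0.541 with an estimated correlation). Endothelial markers fell in 12 of 16 cases and 2 rose, unchanged adjusted over the list alone, with the vascular phosphatase Ptprb at -1.37 ± 0.12 (adjusted p = 0.0106; adjusted p = 0.551 with an estimated correlation). Cardiac muscle markers, which in a lung sample can come from the pulmonary veins, fell in 9 of 12 cases and 1 rose, also adjusted over the list alone, with the atrial myosin gene Myl7 at -1.67 ± 0.24 (adjusted p = 0.0135; adjusted p = 0.616 with an estimated correlation). The largest decreases were in Fabp1 (-3.96 ± 0.43), the endothelial gene Esm1 (-3.59 ± 0.32), Gys2 (-3.44 ± 0.38), Krtap17-1 (-3.23 ± 0.30), Bex2 (-2.81 ± 0.27), Lctl (-2.67 ± 0.46), Itgbl1 (-2.66 ± 0.36) and Tril (-2.42 ± 0.24).

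For ova3_4h 10925 of 19087 genes were called, 4913 higher and 6012 lower, and 734 of these were higher and 365 lower by at least 2-fold. Without the 2 arrays of weaker response the total was 11366. This group, taken on day 30, shared neither the day nor the airway measurement of the control mice.

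The comparison of ova3_24h with the placebo pool concerns the lung a day after the last challenge, the only group that shares its day and its airway measurement with the controls. Goblet cell genes remained far above the pool: Clca1 rose by 9.11 ± 0.24 (553-fold, adjusted p = 2.87e-08), Slc26a4 by 5.81 ± 0.21, Agr2 by 4.81 ± 0.21 and Retnlb, a secreted goblet cell resistin-like protein gene, by 4.77 ± 0.33. All 14 goblet cell and mucus genes rose, also adjusted over the list alone (adjusted p = 5.03e-13; adjusted p = 0.448 with an estimated correlation). Chil3 rose by 5.26 ± 0.27, Chil4 by 4.86 ± 0.30, Retnla by 4.86 ± 0.25 and Arg1 by 4.79 ± 0.41, and 16 of 17 alternatively activated macrophage genes rose, also adjusted over the list alone (adjusted p = 1.69e-11; adjusted p = 0.448 with an estimated correlation). Birc5 rose by 3.39 ± 0.18 and Mki67 by 3.13 ± 0.17, and all 29 cell cycle genes rose by both counts, overall and adjusted over the list alone (adjusted p = 2.69e-19; adjusted p = 0.448 with an estimated correlation).

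Chemokines and Th2 cytokines were still raised. Ccl8 rose by 5.59 ± 0.24 and Cxcl5 by 4.35 ± 0.54; 14 of 17 CC chemokines rose and 1 fell, and 12 of 14 CXC chemokines rose and 2 fell, with the same counts adjusted over the list alone (adjusted p = 1.59e-07 and 9.69e-06; each adjusted p = 0.448 with an estimated correlation). Il5 rose by 2.64 ± 0.40 and Il4 by 1.86 ± 0.35, with 10 of 18 Th2 cytokines and receptors higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.0282; adjusted p = 0.531 with an estimated correlation). The call of that list was lost without ova3_24h replicate 2 (adjusted p = 0.0638). Its mean was 0.204 on ova3_24h replicate 5 against 0.737 on the other 3 arrays.

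Adaptive immune genes were higher too. Foxp3, the regulatory T cell transcription factor, rose by 1.68 ± 0.14 and the checkpoint receptor Ctla4 by 1.82 ± 0.41; 10 of 17 T cell markers rose and 1 fell, also adjusted over the list alone (adjusted p = 0.000885; adjusted p = 0.558 with an estimated correlation). The plasma cell genes Derl3 and Jchain rose by 2.01 ± 0.20 and 1.34 ± 0.26, and Ighm by 1.49 ± 0.31 as the mean of 13 features. Of 15 B cell and plasma cell markers 7 rose, or 5 adjusted over the list alone (adjusted p = 0.0115; adjusted p = 0.616 with an estimated correlation), a call lost without ova3_24h replicate 4 (adjusted p = 0.0659). Cd74, the invariant chain, rose by 1.13 ± 0.11 and the class II gene H2-Eb1 by 0.87 ± 0.08; 9 of 11 genes of MHC class II presentation rose, also adjusted over the list alone (adjusted p = 4.94e-05; adjusted p = 0.531 with an estimated correlation). On ova3_24h replicate 5 the T cell list had a mean of 0.126 against 0.646 on the other 3 arrays, and the B cell and plasma cell list 0.0431 against 0.746. Rnase2a and Prg2 rose by 2.97 ± 0.22 and 2.34 ± 0.28, with 7 of 10 eosinophil markers higher and 1 lower, or 8 and 1 adjusted over the list alone (adjusted p = 0.0022; adjusted p = 0.448 with an estimated correlation). The mast cell protease Mcpt1 rose by 2.25 ± 0.25; 7 of 12 mast cell and basophil markers rose, also adjusted over the list alone (adjusted p = 0.00634; adjusted p = 0.531 with an estimated correlation). Retnlg, a resistin-like gene of neutrophils, rose by 2.70 ± 0.17; 12 of 16 neutrophil markers rose and 1 fell, also adjusted over the list alone (adjusted p = 0.000237; adjusted p = 0.448 with an estimated correlation).

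Genes of xenobiotic metabolism, alveolar type I cells, endothelium and cardiac muscle were also lower at 24 h. Cyp2a5 fell by 2.50 ± 0.17 and Cyp2f2 by 1.81 ± 0.23, and 18 of 22 xenobiotic metabolism genes fell and 2 rose, the same adjusted over the list alone (adjusted p = 0.000247; adjusted p = 0.531 with an estimated correlation). Cav1 (caveolin-1) fell by 0.97 ± 0.12 and Ager, the receptor for advanced glycation end products of type I cells, fell by 0.86 ± 0.10; 9 of 10 alveolar type I markers fell, also adjusted over the list alone (adjusted p = 0.000509; adjusted p = 0.531 with an estimated correlation). Endothelial markers fell in 10 of 16 cases and 1 rose, or 13 and 1 adjusted over the list alone (adjusted p = 0.00579; adjusted p = 0.531 with an estimated correlation). Of 12 cardiac muscle markers 10 fell and 1 rose, also adjusted over the list alone, with Myl7 at -1.52 ± 0.24 (adjusted p = 0.0124; adjusted p = 0.616 with an estimated correlation). Among the largest decreases were those in Gys2 (-3.11 ± 0.38), Lctl (-2.95 ± 0.46), Fabp1 (-2.91 ± 0.43), Esm1 (-2.48 ± 0.32), Glb1l3 (-2.40 ± 0.26) and the matrix gene Omd (-2.19 ± 0.28). In ova3_24h 9910 genes were called, 4205 higher and 5705 lower, with 643 higher and 209 lower by at least 2-fold. Without the 2 arrays of weaker response the total was 10361.

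**Figure D2:**
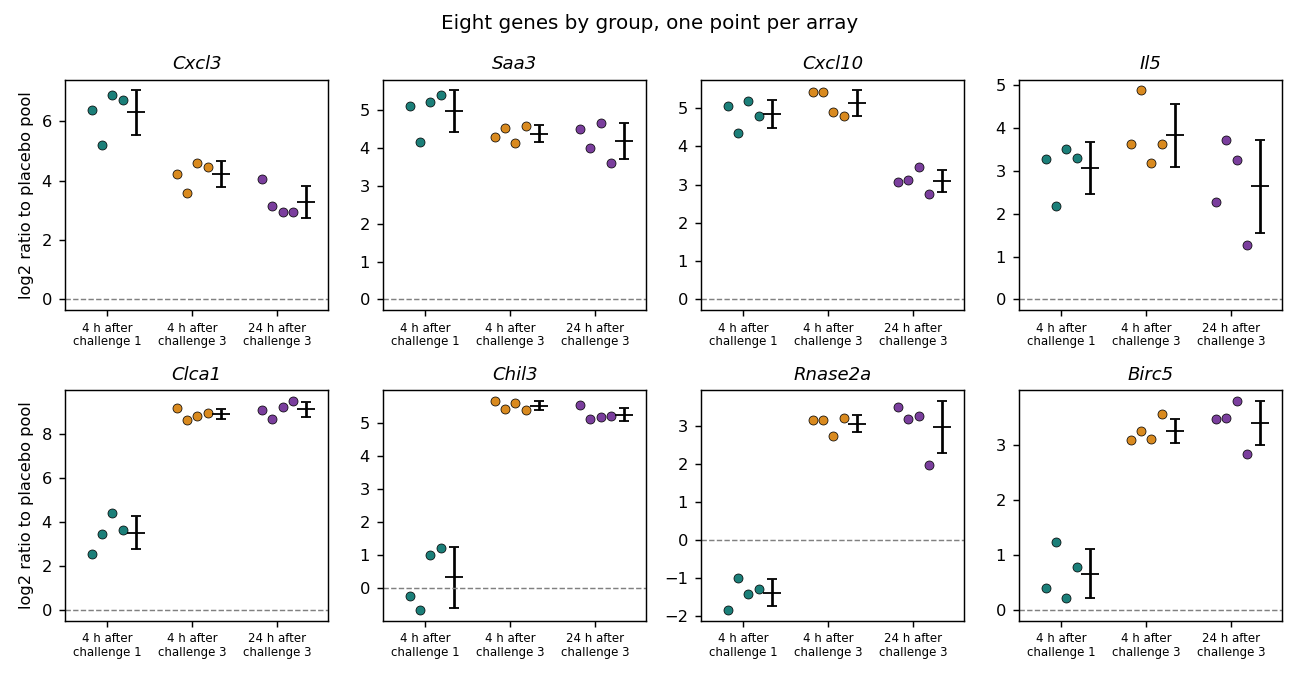
Log2 ratio over the placebo pool of 8 genes, with a point per array and the mean ± SD of each group of 4 arrays. Cxcl3 was highest after challenge 1 with a mean of 6.29, while Clca1 reached means of 8.89 and 9.11 after challenge 3, and Rnase2a went from -1.37 in ova1_4h to 3.06 in ova3_4h.

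The groups at 4 h after challenge 1 and challenge 3 share the interval since the last challenge and differ in the number of challenges and the day. Goblet cell, alternatively activated macrophage and proliferation genes were far higher after challenge 3: Clca1 rose by 5.36 ± 0.34 (41.1-fold, adjusted p = 0.000108), Chil3 by 5.22 ± 0.37, Chil4 by 4.92 ± 0.42, Scin by 3.75 ± 0.20 and Agr2 by 3.30 ± 0.30. The chitinase gene Chia1 rose by 3.14 ± 0.27. Of 14 goblet cell and mucus genes 13 rose, or 14 adjusted over the list alone, and of 17 alternatively activated macrophage genes 15 rose, or 16 adjusted over the list alone (adjusted p = 5.16e-16 and 1.64e-14; each adjusted p = 0.448 with an estimated correlation). Aurkb, Rrm2 and Birc5 rose by 2.82 ± 0.33, 2.61 ± 0.28 and 2.59 ± 0.25, and all 29 cell cycle genes rose, also adjusted over the list alone (adjusted p = 3.41e-24; adjusted p = 0.448 with an estimated correlation).

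Leukocyte genes changed in both directions. Rnase2a rose by 4.43 ± 0.31 (21.6-fold), Prg2 by 2.00 ± 0.39, Alox15 by 3.01 ± 0.29 and the leukotriene C4 synthase gene Ltc4s by 1.40 ± 0.13. Of 10 eosinophil markers 5 rose, also adjusted over the list alone, and of 21 eicosanoid metabolism genes 9 rose and 1 fell, or 11 and 1 adjusted over the list alone (adjusted p = 0.000201 and 4.94e-05; each adjusted p = 0.448 with an estimated correlation). The T cell genes Icos and Zap70 rose by 1.15 ± 0.23 and 0.82 ± 0.18, and 11 of 17 T cell markers rose, or 13 adjusted over the list alone (adjusted p = 5e-07; adjusted p = 0.473 with an estimated correlation). Ifng, the gene of interferon gamma, rose by 1.27 ± 0.22. Ctss rose by 1.86 ± 0.20 and H2-Eb1 by 0.72 ± 0.11; 7 of 11 genes of MHC class II presentation rose, or 9 adjusted over the list alone (adjusted p = 1.14e-06; adjusted p = 0.448 with an estimated correlation). C1qa rose by 1.78 ± 0.20 and Cfp by 1.75 ± 0.16; 5 of 13 complement genes rose, or 8 adjusted over the list alone (adjusted p = 0.00031; adjusted p = 0.531 with an estimated correlation). Neutrophil markers fell in 4 of 16 cases and 1 rose, or 5 and 1 adjusted over the list alone, with the lectin gene Clec4d at -1.16 ± 0.10 and S100a9 at -1.04 ± 0.20 (adjusted p = 0.0219; adjusted p = 0.531 with an estimated correlation).

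Acute phase and inflammatory genes were lower after challenge 3 than after challenge 1. Fgg, a fibrinogen chain gene, fell by 3.24 ± 0.39 (9.44-fold lower), the neutrophil attractants Cxcl2 and Cxcl3 by 2.36 ± 0.46 and 2.08 ± 0.40, the lectin gene Clec4e by 1.93 ± 0.09, the growth factor gene Csf2 by 1.56 ± 0.31 and the haptoglobin gene Hp by 1.51 ± 0.23. Of 25 acute phase and NF-kB response genes 10 fell, or 12 adjusted over the list alone (adjusted p = 0.00058; adjusted p = 0.589 with an estimated correlation). Nmrk2, a nicotinamide riboside kinase gene of muscle, fell by 2.48 ± 0.22, Ppm1n by 2.20 ± 0.21, Itgbl1 by 2.30 ± 0.51 and Esm1 by 2.11 ± 0.45. Cyp2f2 fell by 1.65 ± 0.32, and 9 of 22 xenobiotic metabolism genes fell and 1 rose, or 10 and 3 adjusted over the list alone (adjusted p = 0.0219; adjusted p = 0.648 with an estimated correlation), a call lost without ova1_4h replicate 2 (adjusted p = 0.0752). Myl7 fell by 1.75 ± 0.34 and Ptprb by 0.78 ± 0.17, with 5 of 12 cardiac muscle markers lower, or 7 adjusted over the list alone, and 8 of 16 endothelial markers lower and 1 higher, or 9 and 1 adjusted over the list alone (adjusted p = 0.00197 and 0.00508; adjusted p = 0.558 and adjusted p = 0.531 with an estimated correlation).

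Between these groups 3349 genes were called, 1707 higher and 1642 lower in ova3_4h, with 358 higher and 84 lower by at least 2-fold. The total dropped to 1984 without ova1_4h replicate 1 (1174 higher and 810 lower), 1962 without ova3_4h replicate 2 (1178 and 784) and 1960 without ova3_4h replicate 4 (1145 and 815). It was 4086 without the 2 arrays of weaker response (2023 and 2063). More genes were lower than higher in that last fit, with array weights (2346 higher and 2602 lower) and in a fit of these 2 groups alone (1816 and 1991). The replicate number as a block gave 989 higher and 643 lower. With that block the calls of Cxcl2, Cxcl3, Itgbl1, Esm1, Cyp2f2, Myl7, Icos, Zap70 and Ifng were lost (adjusted p = 0.0537 to 0.0705). Because all arrays share the same pool, comparisons between OVA groups are free of the dye and pool offset.

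The groups at 4 h and 24 h after challenge 3 differ in the time since the last challenge, the day and the airway measurement. Interferon-induced genes were lower at 24 h. Cxcl11 and Cxcl10 fell by 2.21 ± 0.34 (4.62-fold lower, adjusted p = 0.0443) and 2.02 ± 0.22 (4.06-fold lower, adjusted p = 0.026), the immunity-related GTPase genes Iigp1, Igtp and Irgm1 by 1.51 ± 0.21, 1.30 ± 0.16 and 0.57 ± 0.07, the guanylate-binding protein genes Gbp5 and Gbp2 by 1.15 ± 0.17 and 0.70 ± 0.12, Ido1 by 1.52 ± 0.24, Batf2 by 1.18 ± 0.18 and Ifng itself by 1.38 ± 0.22. Of 23 interferon response genes 4 fell, or 6 adjusted over the list alone (adjusted p = 2.84e-05; adjusted p = 0.531 with an estimated correlation). Ccl17 fell by 1.14 ± 0.19, and 1 of 17 CC chemokines fell, or 4 adjusted over the list alone (adjusted p = 8.47e-05; adjusted p = 0.531 with an estimated correlation). Hcar2 fell by 1.26 ± 0.16, Il2ra by 0.71 ± 0.12 and the clock gene Per3 by 0.50 ± 0.04 (adjusted p = 0.00245). Genes that rose included Ldhc (1.21 ± 0.20, at exactly 0 on 4 of the 12 arrays), the keratin gene Krt23 (1.07 ± 0.18), the phosphatase gene Dusp1 (1.00 ± 0.18), Clmp (0.70 ± 0.11) and the chloride channel gene Cftr (0.69 ± 0.11).

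Other changes missed the threshold gene by gene. The heat shock and unfolded protein response list had 17 members that were not called, for example Dnajb9 at -0.96 ± 0.22 (adjusted p = 0.0693) and Ddit3 at -0.55 ± 0.14 (adjusted p = 0.0825). Adjusted over the list alone 9 of them fell, and camera called the list lower (adjusted p = 1.95e-06; adjusted p = 0.513 with an estimated correlation). Il33 differed by -1.64 ± 0.37 (adjusted p = 0.0702) and Il4ra by -0.63 ± 0.16 (adjusted p = 0.0835). The 29 cell cycle genes, such as Mcm7 at 0.25 ± 0.15 (adjusted p = 0.401) and Kif11 at 0.17 ± 0.12 (adjusted p = 0.477), were not called and the list's adjusted p was 0.308, which became 0.00144 without ova3_24h replicate 5 and 0.0242 without ova3_4h replicate 4, with the list higher at 24 h. Between these groups 107 genes were called, 29 higher and 78 lower at 24 h, 2 and 11 of them by at least 2-fold. With the replicate number as a block limma called 0 genes, with 3316 at an unadjusted p under 0.05, and every gene named here as called lost its call (adjusted p = 0.142 to 0.157). Without the 2 arrays of weaker response the count was 1341, and Dnajb9, Ddit3, Il33 and Il4ra were then called (adjusted p = 0.0225, 0.0173, 0.0166 and 0.016). Only ova3_24h replicate 5 of these 2 arrays is in this comparison, and without it alone the count was 129. A fit of these 2 groups alone, which keeps that array and leaves out ova1_4h, gave 1102. The rise to 1341 therefore does not come from that array alone.

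The calls between 4 h and 24 h depended on each array. The count dropped to 1, 1, 2 and 4 without ova3_4h replicate 1, 2, 3 or 4 and to 1, 2 and 1 without ova3_24h replicate 2, 3 or 4, while without ova3_24h replicate 5 it was 129. Per3 kept its call in all 8 of these fits (adjusted p = 0.000726 to 0.0222). Cxcl10 kept it without ova3_4h replicate 4 (adjusted p = 0.0462) and ova3_24h replicate 5 (0.0377), and Ldhc, Clmp, Cxcl11, Iigp1, Igtp, Hcar2, Batf2, Gbp5 and Irgm1 kept theirs without ova3_24h replicate 5 only (0.0377 to 0.0462). The losses in these fits were at an adjusted p of 0.0531 to 0.131. With quantile normalization between arrays 10 genes were called, and of the named ones Cxcl10, Cxcl11, Irgm1 and Ldhc kept their calls, while Per3 had adjusted p = 0.0583. Camera calls of lists at the preset correlation depended on ova3_24h replicate 5 too. Without it, among others, the T cell, MHC class II presentation and eosinophil lists were called higher at 24 h (adjusted p = 0.000187, 0.000382 and 0.0187). Lower calls of the acute phase and NF-kB, alternatively activated macrophage, CXC chemokine and Th2 lists were lost (adjusted p = 0.128, 0.354, 0.202 and 0.161).

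The last comparison, ova3_24h against ova1_4h, spans the number of challenges, the interval, the day and the airway measurement. It mirrored that of ova3_4h with ova1_4h for goblet cell genes: Clca1 rose by 5.59 ± 0.34 (48-fold, adjusted p = 5.84e-05), Mucl1 by 3.71 ± 0.28 and Agr2 by 3.27 ± 0.30, with 12 of 14 members higher, also adjusted over the list alone (adjusted p = 1.17e-13; adjusted p = 0.448 with an estimated correlation). Chil3 and Chil4 rose by 4.95 ± 0.37 and 4.67 ± 0.42, with 15 of 17 alternatively activated macrophage genes higher, and 15 higher and 1 lower adjusted over the list alone (adjusted p = 3.4e-10; adjusted p = 0.448 with an estimated correlation). Esco2, Aurkb and Birc5 rose by 3.03 ± 0.42, 2.92 ± 0.33 and 2.73 ± 0.25, and all 29 cell cycle genes rose, also adjusted over the list alone (adjusted p = 1.14e-22; adjusted p = 0.448 with an estimated correlation). Rnase2a rose by 4.35 ± 0.31, Prg2 by 2.09 ± 0.39 and Ltc4s by 1.60 ± 0.13, with 6 of 10 eosinophil markers higher, also adjusted over the list alone (adjusted p = 1.5e-05; adjusted p = 0.448 with an estimated correlation).

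Antigen presentation and lymphocyte genes were higher at 24 h after challenge 3. The peptide-loading gene H2-DMb1 rose by 0.88 ± 0.10 and Ctss by 1.84 ± 0.20, and 10 of 11 genes of MHC class II presentation rose, or 11 adjusted over the list alone (adjusted p = 6.32e-08; adjusted p = 0.448 with an estimated correlation). Mzb1 and Derl3, genes of antibody-secreting cells, rose by 1.54 ± 0.29 and 1.24 ± 0.28, and 7 of 15 B cell and plasma cell markers rose, or 10 adjusted over the list alone (adjusted p = 0.00031; adjusted p = 0.531 with an estimated correlation). Icos rose by 0.99 ± 0.23, and 12 of 17 T cell markers rose, or 13 adjusted over the list alone (adjusted p = 1.93e-07; adjusted p = 0.455 with an estimated correlation).

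Early inflammatory genes were lower at 24 h after challenge 3. Fgg fell by 4.65 ± 0.39 (25-fold lower), Cxcl3 by 3.02 ± 0.40, Cxcl2 by 2.85 ± 0.46, Clec4e by 2.04 ± 0.09, Hp by 1.87 ± 0.23, Csf2 by 1.78 ± 0.31 and the interleukin-1 alpha gene Il1a by 1.52 ± 0.21. Of 25 acute phase and NF-kB response genes 15 fell and 1 rose, or 16 and 1 adjusted over the list alone (adjusted p = 1.48e-05; adjusted p = 0.531 with an estimated correlation). Rsad2, Gbp2 and Ifit1 fell by 1.25 ± 0.26, 0.95 ± 0.12 and 0.88 ± 0.12, with 9 of 23 interferon response genes lower, or 12 adjusted over the list alone (adjusted p = 0.000685; adjusted p = 0.558 with an estimated correlation). Nmrk2 fell by 2.68 ± 0.22, Gsta3 by 1.35 ± 0.24, Myl7 by 1.60 ± 0.34 and the vascular growth factor gene Vegfa by 0.87 ± 0.13. In all, 4680 genes were called, 2221 higher and 2459 lower, with 416 higher and 125 lower by at least 2-fold. More genes were higher than lower without ova1_4h replicate 1 (1788 higher and 1750 lower) or 5 (1824 and 1757), without ova3_24h replicate 2 (1729 and 1713) or 4 (1729 and 1631), in a fit of these 2 groups alone (1656 and 1557) and with the replicate block (1612 and 1501), under which Icos and Rsad2 lost their calls (adjusted p = 0.0589 and 0.0535). Without the 2 arrays of weaker response the total was 6170.

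**Figure D3:**
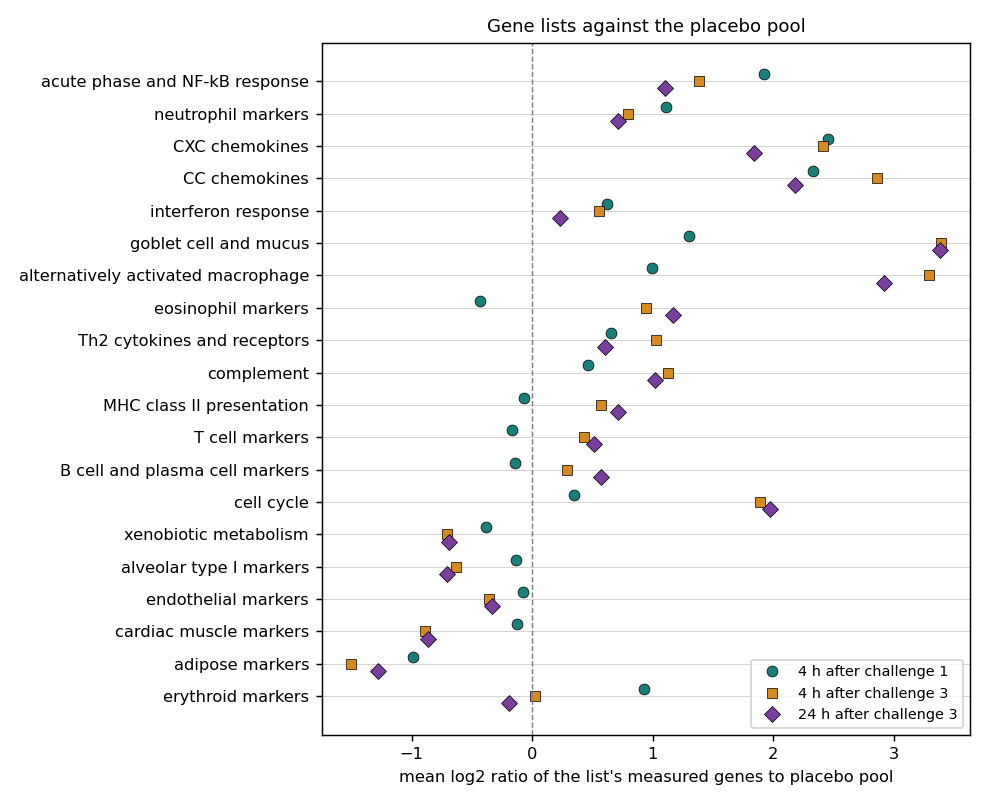
Mean log2 ratio over the placebo pool of the measured members of 20 gene lists in the 3 groups, each from 4 arrays. The goblet cell and mucus list went from 1.30 in ova1_4h to 3.39 and 3.38 after challenge 3, the cell cycle list from 0.35 to 1.89 and 1.97, and the acute phase and NF-kB response list from 1.92 to 1.38 and 1.10.

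Many calls against the pool were shared by the groups. In all 3 groups 1928 genes were higher and 2716 lower, and 223 of these 4644 changed at least 2-fold in each group, 177 higher and 46 lower. From ova1_4h to ova3_4h 2606 higher and 3357 lower calls were shared, where independent calls would give 906 and 1327. From ova3_4h to ova3_24h 3470 higher and 4595 lower calls were shared against 1082 and 1797, and from ova1_4h to ova3_24h 2015 and 2829 against 775.5 and 1260. The changes of these pairs of groups correlated across genes at 0.739, 0.924 and 0.619, and genes are not independent replicates. A shared control alone makes such correlations: 20 simulations without any effect but with a common pool of 6 mice gave 0.4, 0.405 and 0.402. The simulated covariances of 0.00752, 0.00766 and 0.00759 compare with 0.159, 0.261 and 0.119 in the data. The simulated values follow from the settings: the pool error was taken from the spread within the OVA groups. Dye bias and other peculiarities of the pool were not simulated. The gap therefore cannot separate these from a response shared by the groups. Of the shared genes 3338 were not called between any of the groups.

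**Figure D4:**
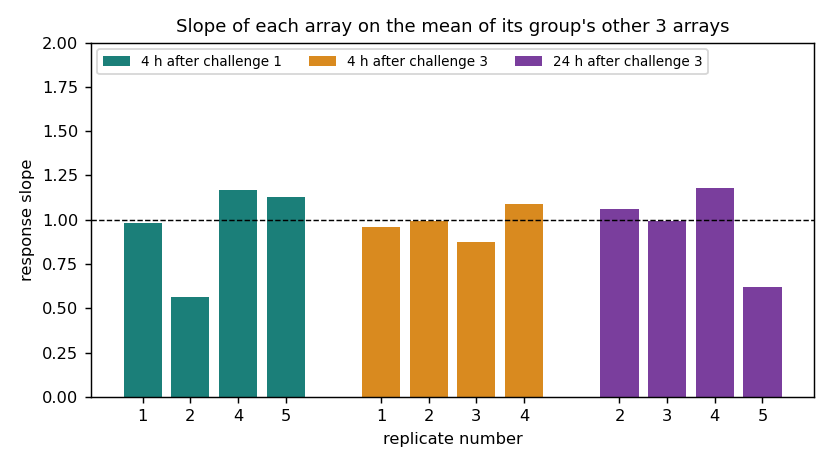
Response slope of each of the 12 arrays, the slope of its gene changes on the mean of the other 3 arrays of its group, with a dashed line at 1. The slopes of ova1_4h replicate 2 (0.565) and ova3_24h replicate 5 (0.62) lay below the range of 0.873 to 1.18 of the other arrays.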

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

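The tests of placebo RNA mixed into either of the 2 arrays, of a response scaled alike on either of them, and of fat in the pool alone were chosen after the results they measure were seen; the other tests in this part were set beforehand. A first form of the test of a response scaled alike, over all lists with at least 10 members, was replaced because all 12 arrays exceeded its bound of 1.5. On ova3_24h replicate 5 its ratios ran from 0.0578 (B cell and plasma cell) to 1.18 (macrophage and monocyte), a factor of 20.4 against 1.53 to 8.35 on the other 10 arrays. On ova1_4h replicate 2 they ran from -0.00378 (heat shock and unfolded protein response) to 2.56 (cell cycle).

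Responses on ova1_4h replicate 2 and ova3_24h replicate 5 were weaker than on the other arrays of their groups, with response slopes of 0.565 and 0.62. Ratios compressed by labelling or scanning are argued against by features without a listed gene that were steady on the other 11 arrays, whose slopes on these 2 arrays were 1 and 1.01, against 0.987 to 1.01 on the rest. For ova1_4h replicate 2, a placebo share of 43.2%, set from the lowered genes, predicts -0.728 for the raised genes. Their median was -1.25 ± 0.14, an excess of -0.521. This ± is a standard error over 37 genes of 1 array, which are not independent, and it leaves out the error of the share. The excess goes against placebo-type RNA as the whole source, but with such an error it cannot decide. Over the lists with a mean of at least 1 on the other 3 arrays, the ratios of ova1_4h replicate 2 from 0.329 (alternatively activated macrophage) to 0.876 (neutrophil markers) span a factor of 2.66, beyond the 1.1 to 1.73 of the other 10 arrays (SD 0.19), which argues against a response scaled down alike. A second test took, over the lists called higher, the SD of the observed minus the predicted list mean, with each array's own placebo share or slope. The other 10 arrays gave 0.103 to 0.247 (SD 0.042) for a mixture and 0.1 to 0.227 (SD 0.038) for scaling. On ova1_4h replicate 2 the values of 0.268 and 0.261 exceeded these ranges by less than their SD and decide nothing.

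For ova3_24h replicate 5, a response scaled down alike is argued against by the second test, with 0.317 beyond the range of the other arrays by more than its SD. The goblet cell and mucus list was at 3.23 where its slope predicts 2.13, and the B cell and plasma cell list at 0.0431 where it predicts 0.463. Its factor of 1.8 over the lists with a mean of at least 1, from 0.522 (eosinophil markers) to 0.941 (goblet cell and mucus), was by itself within an SD of the other arrays. Placebo-type lung RNA stays open. The array's value of 0.189 in the second test was within the range. A share of 43.5% predicts -0.72 and the raised genes were at -0.847 ± 0.089 (again a standard error over genes), a difference of -0.127. The goblet cell and mucus list went against a mixture, at 3.23 where the mixture predicts 2.80, an excess of 0.43 that ova1_4h replicate 4 also showed (0.428), and Clca1 was at 9.50 against 8.67 to 9.20 on the other 3 arrays. The labels name no difference between these samples and the others, and no biological explanation was tested.

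Adipose markers were below the placebo pool in all groups: 7 of 10 fell in ova1_4h, 9 in ova3_4h and 8 in ova3_24h, or 8, 9 and 9 adjusted over the list alone (adjusted p = 0.00512, 0.00315 and 0.00506; adjusted p = 0.552, adjusted p = 0.531 and adjusted p = 0.552 with an estimated correlation), with the lipid droplet gene Plin1 at -1.60 ± 0.29, -2.31 ± 0.29 and -1.90 ± 0.29 and Adipoq at -1.97 ± 0.34 and -1.91 ± 0.34 after challenge 3. Adipoq also fell in ova1_4h (-1.17 ± 0.34), a call lost without ova1_4h replicate 4 (adjusted p = 0.0962) or 5 (0.0832). Residuals of the 10 markers within groups had a median pairwise correlation of 0.768, against a 95th percentile of 0.139 in 1000 random lists and 0 of them as high. Fat content differing from sample to sample would give this, but so would a response differing in strength. The markers were least lowered in their groups on ova1_4h replicate 2 (-0.565) and ova3_24h replicate 5 (-0.851). Yet ova3_4h replicates 1 and 2, with slopes of 0.959 and 0.994, were at -0.981 and -2.07. Correlation within groups cannot account for means below the pool in all groups. More fat tissue in the placebo pool alone would give all groups the same mean, and the largest difference between the groups' means, -0.988 and -1.50, was 1.63 standard errors, which leaves it undecided. A response of lung fat or of lipid genes to OVA stays open as untested, and Fabp4 also stands in another list.

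Many genes were called in the same direction in all 3 groups against the pool with no call between groups: 3338, of which 2913, or 87.3%, changed less than 2-fold in each group. A dye or pool offset common to all arrays cannot be told apart from a lasting response to OVA, since no dyes were swapped and all arrays share the same pool.

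For the counts between groups, 1 of the 35 splits of the 8 arrays, the real one, gave as many genes for ova3_4h against ova1_4h (3349, highest other 1), for ova3_24h against ova3_4h (107, highest other 7) and for ova3_24h against ova1_4h (4680, highest other 1). A share of 1 in 35 is the smallest these splits can give, and mixed splits carry the group difference into their spread. The splits alone therefore cannot exclude chance. The count of 107 also fell to 0 with the replicate block and to as few as 1 with an array left out.

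Far from the other 3 arrays of their group were 22 values of 305 groups of 4 tested, or 1.44 per 20, where chance gives about 1 in 20. On ova1_4h replicate 2 these were the residual SD (0.241, others 0.168 to 0.179), Bex2 (-1.78, others -3.01 to -2.80), Ccl7 (4.38, others 5.10 to 5.23), Cxcl11 (3.42, others 4.52 to 4.58), Cxcl2 (2.64, others 4.15 to 4.45), Hp (0.761, others 1.71 to 1.89), Ltc4s (-0.993, others -1.42 to -1.38), Ppm1n (2.08, others 1.38 to 1.39) and Retnla (2.91, others 4.60 to 4.77). Clec4d was high on ova1_4h replicate 5 (1.53, others 1.20 to 1.23) and Fgg low on ova1_4h replicate 4 (1.88, others 2.72 to 2.86). In ova3_4h, replicate 4 stood apart for Aurkb (3.55, others 3.07 to 3.15) and Hopx (-1.09, others -0.93 to -0.897), replicate 1 for Ccl17 (3.49, others 2.99 to 3.01) and Kif11 (0.96, others 0.804 to 0.816), and replicate 3 for Il33 (2.85, others 3.24 to 3.31), Prg2 (1.25, others 2.54 to 2.61) and Rnase2a (2.72, others 3.15 to 3.21). In ova3_24h, replicate 5 stood apart for Glb1l3 (-1.18, others -2.88 to -2.72) and Nmrk2 (-0.654, others -1.74 to -1.63), and replicate 3 for Rsad2 (-0.449, others 0.227 to 0.293) and Scin (3.72, others 4.25 to 4.35).

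Opposite calls against the pool, with a called difference between the groups, were found for 229 genes between ova1_4h and ova3_4h, 510 between ova1_4h and ova3_24h and 28 between ova3_4h and ova3_24h. Rnase2a was lower in ova1_4h (-1.37) and higher after challenge 3, by 4.43 at 4 h and 4.35 at 24 h relative to ova1_4h. Nmrk2 was higher in ova1_4h (1.25) and lower later, with differences of -2.48 and -2.68. The scavenger receptor gene Marco was higher in ova1_4h (1.16) and lower in ova3_4h (-1.16) and ova3_24h (-1.40), with differences of -2.32 and -2.56, though its call in ova3_4h was lost without replicate 2, 3 or 4 (adjusted p = 0.0543, 0.0647 and 0.0675), and with the replicate block that call and the difference from ova1_4h to ova3_4h were lost (adjusted p = 0.0745 and 0.0641). Vegfa was higher in ova1_4h (0.283) and lower in ova3_4h (-0.365) and ova3_24h (-0.586), with differences of -0.648 and -0.868. From ova1_4h to ova3_4h, Ppm1n went from 1.56 to -0.642, a difference of -2.20, and Clmp from 0.514 to -0.215, a difference of -0.729. From ova1_4h to ova3_24h, Fgg went from 2.55 to -2.10 (difference -4.65), Il1a from 1.11 to -0.408 (-1.52), Hcar2 from 1.08 to -0.292 (-1.37), Ddit3 from 0.273 to -0.742 (-1.02) and Ltc4s from -1.30 to 0.301 (1.60). Of these genes, Ddit3 in ova1_4h and Ltc4s and Marco in ova3_24h showed the direction on 3 of the 4 arrays. From ova3_4h to ova3_24h, Clmp went from -0.215 to 0.487 (0.702) and Hcar2 from 0.965 to -0.292 (-1.26), differences that were called with all 8 arrays and in at most 1 of the fits with an array left out (Clmp adjusted p = 0.0377 and Hcar2 0.0426 without ova3_24h replicate 5).

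Features without a listed gene, which no gene test used, were also called: of 11309, 386 differed from the pool by at least 2-fold in ova1_4h (226 higher and 160 lower), 612 in ova3_4h (343 and 269) and 516 in ova3_24h (337 and 179), at most 11.1-fold, 23-fold and 19.9-fold higher. The 11309 include features steady on all arrays, with 32 at a mean log10 ratio of -0.809, 132 at -0.326, 100 at 0.547 and 42 at 0.968. Such steady features show no response to OVA. They were not taken out, so the counts overstate the features that changed. The overstatement can be large: 32 and 132 steady features lie on the lower side, where 160 features were called in ova1_4h. How many calls remain without the steady features was not counted.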

How the results depend on the processing

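Leaving out features at 0 before averaging and leaving out the 2 arrays of weaker response were chosen after the data were seen; the other alternatives here were planned. Signal over background was not analysed here, and the number of arrays limits all results. None of the 252 gene results taken by the rule reversed its direction under the alternatives run for it. Of these, 200 kept their direction and side of the threshold under every setting run for them, and 2534 of 2790 values did. Feature by feature, the feature with the smallest p stood for its gene, so other features going the opposite way were not counted. For example, feature 30576 of Pon1 was at 0.71 in ova3_4h, where the gene value was -1.20. Weaker were 184 values with an array left out, 42 with the replicate block, 15 with quantile normalization (all between 4 h and 24 h after challenge 3), 1 feature by feature and 1 without the 2 weak arrays. Counts against the placebo pool stayed within 1.5 times the reported ones, except for ova1_4h in a fit of its own arrays alone (4720). The same kind of fit gave 10634 for ova3_4h and 7890 for ova3_24h. The smaller number of arrays therefore does not by itself account for the drop in ova1_4h. With an array left out the counts against the pool ran from 5770 to 7709 for ova1_4h, from 9564 to 10011 for ova3_4h and from 8216 to 9829 for ova3_24h.

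Between groups, leaving out an array gave 1960 to 3017 genes for ova3_4h against ova1_4h, 1 to 129 for ova3_24h against ova3_4h and 3360 to 5518 for ova3_24h against ova1_4h. The count of 107 genes between 4 h and 24 h after challenge 3 moved most: to 10 with quantile normalization, 47 with robust moderation, 58 without the genes in the lowest quartile of spread (fewer genes tested), 62 without features at 0, 1102 in a fit of these 2 groups alone, 1341 without the weak arrays and 1377 with array weights. All 107 genes remained called in the last 3. Of the weak arrays only ova3_24h replicate 5 is in this comparison, and leaving it out alone gave 129. The balance of higher and lower calls turned over in both comparisons with ova1_4h. For ova3_4h, 1707 higher and 1642 lower became 2346 and 2602 with array weights, 1816 and 1991 in a fit of the 2 groups alone and 2023 and 2063 without the weak arrays, while the replicate block gave 989 and 643. For ova3_24h, 2221 higher and 2459 lower became 1612 and 1501 with the replicate block, 1656 and 1557 in a fit of the 2 groups alone, 2545 each with quantile normalization, 1788 and 1750 without ova1_4h replicate 1, 1824 and 1757 without ova1_4h replicate 5, 1729 and 1713 without ova3_24h replicate 2 and 1729 and 1631 without ova3_24h replicate 4. Except where stated the cause was not tested.

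The replicate numbers of the titles do not appear to pair the samples: over 9 pairs with the same number the residual correlation ran from -0.195 to 0.321, and 3 of 12 arrays were closest to an array of their own number. The description of ova1_4h replicate 4 calls it the third sample. Its residual correlation was -0.146 and 0.0846 with replicate 3 of ova3_4h and ova3_24h, and 0.115 and 0.119 with their replicate 4. The block was run with the title numbers only. With the replicate block limma called 1632 genes for ova3_4h against ova1_4h and 3113 for ova3_24h against ova1_4h. For ova3_24h against ova3_4h it called 0, with 3316 at an unadjusted p under 0.05. A block leaves fewer degrees of freedom for the spread, which by itself can lower the counts. How far this accounts for the drop was not tested. Gene list calls ran from 122 to 129 with an array left out and from 124 to 130 under the other settings, except the estimated correlation, under which camera called 0 with 26 at an unadjusted p under 0.05. Requiring 2-fold reduced the shared calls from 4644 to 223, by construction.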

Other observations

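The gene lists here were fixed before the data were examined, and no explanation was tested for them. Clock genes were lower a day after challenge 3: the transcription factor gene Dbp fell by 1.49 ± 0.22 and Per1 by 1.35 ± 0.25 against the pool, while Nfil3, a repressor of the same promoter elements, rose by 1.53 ± 0.28. Of 17 circadian clock genes 11 fell and 4 rose in ova3_24h, or 12 and 4 adjusted over the list alone (adjusted p = 0.029; adjusted p = 0.531 with an estimated correlation). From ova1_4h to ova3_24h 8 fell and 2 rose, or 9 and 2 adjusted over the list alone (adjusted p = 0.00747; adjusted p = 0.513 with an estimated correlation), with Per2 at -0.80 ± 0.14, Ciart at -1.12 ± 0.23 and Arntl, a gene of the opposite phase, at 0.97 ± 0.24, a call lost with the replicate block (adjusted p = 0.0738). The hour of the day at which lungs were taken is not given in the sources used here.

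Red cell genes were higher after challenge 1. Hba-a1 and Hba-a2, which encode alpha globin, rose by 1.22 ± 0.28 each in ova1_4h, and 6 of 7 erythroid markers rose, or 7 adjusted over the list alone (adjusted p = 0.00477; adjusted p = 0.453 with an estimated correlation). In ova3_4h and ova3_24h the 7 markers were not called and the list had adjusted p = 0.812 and 0.78; Alas2 was at -0.35 ± 0.25 and -0.63 ± 0.25, and Hba-a2 in ova3_24h at -0.57 (adjusted p = 0.12). Without ova3_24h replicate 5 both genes were called lower in ova3_24h (Alas2 -0.86, adjusted p = 0.0213; Hba-a2 -0.85, adjusted p = 0.0321), as they were without the 2 weak arrays (adjusted p = 0.0159 and 0.0335). Alas2 was also called with features at 0 left out before averaging (adjusted p = 0.036). Over its other alternatives its adjusted p was 0.0573 to 0.262, against 0.0824 to 0.503 for Hba-a2. Compared with ova1_4h, Hba-a1 and Hba-a2 fell by 1.66 ± 0.40 and 1.79 ± 0.40 in ova3_24h, with 3 of 7 markers lower, or 7 adjusted over the list alone (adjusted p = 0.00576; adjusted p = 0.455 with an estimated correlation), and Hbb-bt, a beta globin gene, fell by 1.94 ± 0.44.

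Stress genes were higher 4 h after challenge 1 and challenge 3, and matrix genes in all groups. In ova1_4h 10 of 17 heat shock and unfolded protein response genes rose and 1 fell, or 11 and 1 adjusted over the list alone (adjusted p = 0.00178; adjusted p = 0.574 with an estimated correlation). The mean of the list was -0.00257 on ova1_4h replicate 2 against 0.681 on the other 3 arrays. The counts were 10 and 1 in ova3_4h, also adjusted over the list alone (adjusted p = 0.0117; adjusted p = 0.626 with an estimated correlation), and in ova3_24h 3 rose and 5 fell, also adjusted over the list alone, with no call of the list (adjusted p = 0.899). Timp1, a metalloproteinase inhibitor gene, rose by 3.15 ± 0.32 in ova1_4h; 11, 14 and 17 of 22 extracellular matrix and remodelling genes rose and 1, 2 and 1 fell in ova1_4h, ova3_4h and ova3_24h, and adjusted over the list alone 11, 14 and 17 rose and 1, 2 and 2 fell (adjusted p = 0.00576, 0.000761 and 4.4e-05; adjusted p = 0.616, adjusted p = 0.558 and adjusted p = 0.531 with an estimated correlation). Antioxidant enzyme genes went both ways, with 12, 14 and 12 of 21 higher and 5 lower in each group, or 6, 5 and 5 lower adjusted over the list alone with the same numbers higher (adjusted p = 0.00641, 0.00642 and 0.0248; adjusted p = 0.473, adjusted p = 0.473 and adjusted p = 0.531 with an estimated correlation).

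Markers of several tissues and cell types gave no call in any group against the pool. For ova3_24h, 4 of 13 alveolar type II markers rose and 7 fell (adjusted p = 0.736), 4 of 10 smooth muscle markers rose and 2 fell (adjusted p = 0.195), 2 of 9 thymocyte markers rose and 3 fell (adjusted p = 0.76), and 1 of 8 liver markers rose and 2 fell (adjusted p = 0.851); adjusted over the list alone the counts were 4 and 7, 5 and 2, 2 and 3, and 1 and 2. Club cell markers rose in 4 of 10 cases and 3 fell, also adjusted over the list alone, with a median of -0.09, a mean of -0.11 and a test direction that was positive (adjusted p = 0.645). The skeletal muscle list, in contrast, was called by camera in each group. Its markers fell in 7, 10 and 8 of 12 cases and 1, 1 and 2 rose in ova1_4h, ova3_4h and ova3_24h. Adjusted over the list alone 7, 10 and 9 fell and 1, 1 and 2 rose. The list had adjusted p = 0.0152, 0.0124 and 0.0204 by camera, and each became adjusted p = 0.531 with an estimated correlation.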
